A study of Mus musculus with 6 samples.

How the data were processed

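The values used were the deposited log2 levels of 35557 probe sets on each of 6 arrays, made by RMA per the submitters' processing notes. A second deposited table held linear intensity for the authors' list of 52 probe sets, and its values equalled 2 to the power of the log2 levels within 4.9e-06. Per the labels, tissue was kept in RNAlater, frozen and laser captured, RNA was extracted with Trizol, and amplified cRNA was turned into biotin-labelled single-stranded cDNA. The software of the RMA step and its version are not given in the labels. The sorted arrays differed from their mean by a median of 0.0216, so the values were used without further normalization.

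Of the 35557 probe sets, 21789 had 1 gene symbol in the probe table, 1621 had several and 12147 had none. The RefSeq gene table of assembly GRCm38.p6 was used only for names; it held the Entrez id of 21698 probe sets and changed 0 symbols. For each gene the probe set with the highest mean over the 6 arrays was kept, which gave 19938 genes, 999 of them with over 1 probe set. No filter on dim genes was set. No coordinates are given, since the labels name no genome build.

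Tests were run in R 4.3.3 with limma 3.58.1. The genotype and age comparisons came from 1 lmFit and eBayes model with genotype and age as a 3-level factor (2 residual degrees of freedom and 7.51 prior degrees of freedom). The slope comparison used genotype, postnatal day as a number and their product. All p-values are 2-sided, and adjusted p is by Benjamini-Hochberg over the genes or lists of a comparison, with a threshold of 0.05. Gene lists were tested with limma camera at a preset inter-gene correlation of 0.01, and again with a correlation estimated from the residuals. Members were also counted when adjusted over the list alone. Single ages had 1 array per genotype and no test. There each list's median was placed among 10000 random lists of the same size and mean level. Their genes were drawn singly, so a rank does not allow for correlated members or for the spread between captures. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

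The 21 gene lists, the tests, the alternatives and the rule for naming genes were written before the data were examined. The lists held 530 symbols, of which 489 were measured. They covered the axoneme, dynein assembly, multiciliation regulators, intraflagellar transport, ependymal surface and polarity, choroid plexus, hedgehog signalling, proliferation, the other cell types a capture could hold, reactive states and sex chromosome genes. By the rule, Foxj1 was named before others, then up to 12 genes per direction with the largest mean difference among those that passed with 1 sign at all ages, filled by the smallest p where fewer passed. It also named up to 4 members per list with the largest absolute genotype difference. For day 14 against day 1 it named 12 genes per direction, only among those with the same sign in both genotypes. The slopes and each age had 6 per direction, and the authors' list its leading 5. List members named as examples for the age comparison were those with a large passing change and were chosen after their values were seen, as were Folr1 and the axoneme members that did not pass.

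The same code was run on simulated values for 19938 genes with 200 changed. For the genotype comparison it recovered 0% of changes of 0.5, 99% of changes of 1 (14 false among 212 calls) and 100% of changes of 2. For day 14 against day 1 the shares were 0%, 91% and 99.5%, and for a total slope difference over the 13 days 0%, 0% and 93%. All 10 lists of 20 genes shifted by 0.3 were recovered and 0 of 10 unshifted lists were called. The simulated genes were drawn independently of each other. In the data, the correlation estimated for the genotype comparison ran from -0.0511 (dynein assembly) to 0.95 (meningeal genes). The simulated list result therefore does not cover lists with correlated members.

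Alternatives changed 1 choice at a time, except the fit without the wildtype day 1 and null day 7 arrays, in which age was also made linear because 4 arrays leave no residual degree of freedom with age as a factor. The others were a further quantile normalization, centring each array on its median, leaving out the lowest tertile of genes or those below the median, the mean of all probe sets of a gene, each probe set on its own, an intensity trend or a robust prior in eBayes, age as a linear covariate or left out, genotype left out, log2 of postnatal day, an estimated correlation, and leaving out arrays. Xist as a covariate, the fit without the wildtype day 1 and null day 7 arrays, and leaving out single arrays for the age and slope lists were added after the data were seen. Probe sets without 1 named gene were not used in the comparisons.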

Results

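Gene expression was measured in the ependymal layer of the mouse brain, the ciliated epithelium that lines the ventricles, with 6 Affymetrix whole-transcript arrays. The tissue was the EGFP-positive domain of FoxJ1-EGFP brains, in which the fluorescent protein reports activity of the Foxj1 gene, and it was taken by laser capture. Foxj1 encodes a forkhead transcription factor of the motile cilia programme. The arrays covered 2 genotypes, wildtype and FoxJ1 null, at postnatal days 1, 7 and 14, with 1 array per genotype and age, so that 3 arrays stood for each genotype and 2 for each age. Median log2 levels over all probe sets lay between 7.72 (wildtype day 7) and 7.81 (wildtype day 14). The number of arrays limits the precision. The labels do not say whether an array held 1 animal or a pool, or whether any arrays shared an animal; p-values therefore measure the spread between these arrays. Differences are log2 values, FoxJ1 null minus wildtype, and an SD is taken over the 3 ages (n = 3 pairs of arrays) unless another error is named.

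The targeted gene was examined before the others. Foxj1 (probe set 10393266) was lower in the null array at each age, by -0.79 at day 1, -0.78 at day 7 and -0.34 at day 14, a mean difference of -0.63 ± 0.25 (SD) or 1.55-fold. Its levels were 6.89, 6.95 and 6.90 on the null arrays of days 1, 7 and 14 and 7.68, 7.72 and 7.24 on the wildtype arrays. The difference did not pass the limma test (adjusted p = 0.0573), and over 13 alternative settings the adjusted p ran from 0.00531 to 0.468, with 4 settings below the threshold. The position of the probe set relative to the deleted part of the gene is not given in the sources used here, so the value is an open check of the labels.

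The series title names male mice, and Xist, the X-inactivation transcript, was high on 2 arrays. It read 12.40 on the wildtype day 1 array and 12.35 on the null day 7 array, against 5.37 to 5.83 on the other 4. The Y-linked genes Eif2s3y, Kdm5d and Uty read 4.53 to 5.21 on those 2 arrays and 8.94 to 10.72 on the others. Each genotype held 1 array of this kind, and so did days 1 and 7, while day 14 held none. The sex-chromosome list joins Xist with these 3 genes, from which it moved in the opposite direction, so its limma camera tests decide nothing (adjusted p = 0.838 between the genotypes, 0.44 between days 14 and 1 and 0.187 for slopes). Fits with Xist as a covariate, or without these 2 arrays and with age as a linear covariate, are given below where they changed a call, its direction or a count by over 1.5 times.

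**Figure D1:**
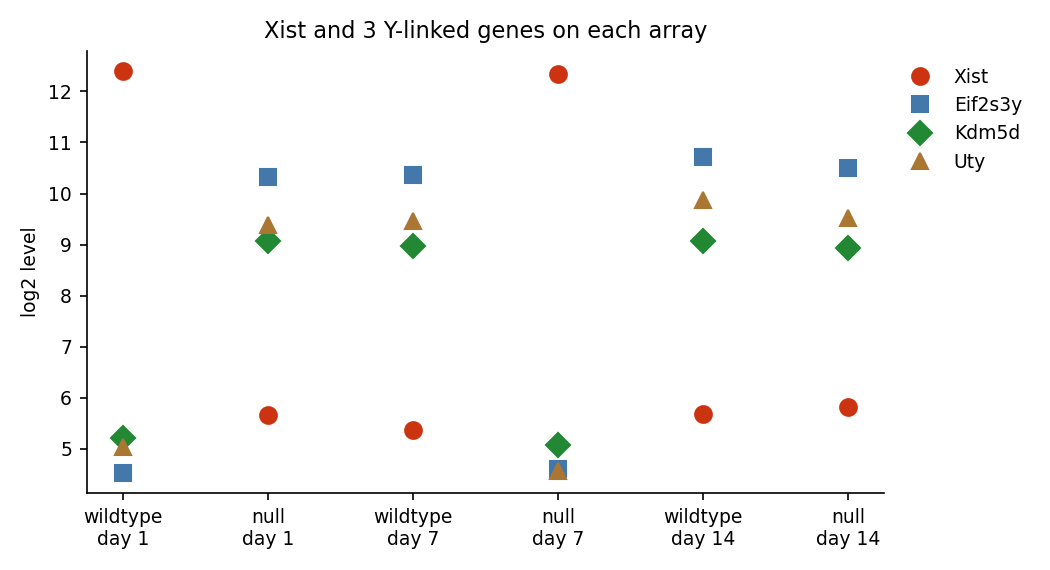
Log2 level of Xist and of 3 Y-linked genes on each of the 6 arrays, which are placed along the horizontal axis. Xist read above 12 and the Y-linked genes at 5.21 or below on the wildtype day 1 and null day 7 arrays.

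Loss of Foxj1 was accompanied by lower levels of genes of the motile cilium at all 3 ages. Fam216b had the greatest difference, -2.84 ± 0.18 (SD), a level 7.16-fold lower in the null arrays (limma adjusted p = 7.25e-06). Dnah12, an axonemal dynein heavy chain, was lower by 4.79-fold (-2.26 ± 0.09, adjusted p = 1.56e-05), and Bbox1, the last enzyme of carnitine synthesis, by 4.61-fold (-2.20 ± 0.24, adjusted p = 4.93e-05). Ak7, an adenylate kinase of motile cilia, was lower by 3.98-fold (-1.99 ± 0.29) and the radial spoke head gene Rsph4a by 3.81-fold (-1.93 ± 0.18). Olfr859, an olfactory receptor with a mean log2 level of 4.85, was higher by 0.59 ± 0.03 (adjusted p = 0.0277).

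Of 19938 genes, 134 differed between the genotypes, 133 lower and 1 higher in the null. All 133 were lower at each of the 3 ages, with mean folds from 1.48 to 7.16, and 58 were at least 2-fold lower. The test weighs a mean difference against its spread over the ages and so favours genes of 1 sign. The shared sign is therefore not separate evidence. Over all genes tested, 3172 (15.9%) were lower and 1576 (7.91%) higher at each age, against 15.6% and 9.05% from multiplying the shares of genes lower or higher at the 3 ages. Among the other genes named by the fixed rule were Cfap44 (-1.88 ± 0.48) and Cfap43 (-1.84 ± 0.16), which encode cilia and flagella associated proteins, and Odf3b (-1.75 ± 0.21). Tmem212 (-1.73 ± 0.62), Enkur (-1.71 ± 0.42), Spata18 (-1.69 ± 0.17) and Capsl (-1.63 ± 0.32) completed the 12 greatest decreases. No gene besides Olfr859 was called higher, against 6 with each array centred on its median and 11, 11 and 14 without the arrays of day 1, 7 or 14. Those with the smallest p and the same sign at all ages were Casq1, a calcium-binding protein of muscle (0.53 ± 0.08, adjusted p = 0.0579), Olfr1418 (0.58 ± 0.20, adjusted p = 0.0612), 1700093K21Rik (0.64 ± 0.34, adjusted p = 0.0933), 3830403N18Rik (0.52 ± 0.21, adjusted p = 0.118) and Tex35 (0.68 ± 0.42, adjusted p = 0.128). Gm1604a, Pcdhb9, 4930558K02Rik, Ms4a6b, BC018473 and the neuropeptide gene Tac1 followed, with adjusted p from 0.13 to 0.187. At an unadjusted p under 0.05, 1180 genes passed. Without the wildtype day 1 and null day 7 arrays, and with age as a linear covariate, 66 genes were called, 61 of them among the 134, and with Xist as a covariate 156, 126 of them among the 134. The count fell to 45 with age left out of the model and to 16 when genes below the median level were left out, and Olfr859 was not called in 4 of 12 alternatives, the fit without the 2 high-Xist arrays (0.71, adjusted p = 0.139) among them.

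The axoneme list, 99 measured genes of the motile cilium's microtubule core and its beat machinery, was lower as a group. All 99 members had a negative mean difference, the median was -0.72, 57 passed the test over all genes and 88 passed when adjusted over the list alone. Dnah12, Ak7, Cfap44 and Rsph4a had the greatest decreases. Several members did not pass, among them Dnah8 (-0.04, adjusted p = 1.00), Ropn1l (-0.08, adjusted p = 1.00) and Drc1 (-0.12, adjusted p = 1.00), examples chosen after their values were seen. By camera the list had an adjusted p of 3.30e-128 at the preset correlation and adjusted p = 0.0777 with an estimated correlation. The median difference was -0.85 at day 1, -0.70 at day 7 and -0.74 at day 14, below all 10000 random lists of the same size and mean level at each age. Without the 2 high-Xist arrays and with age linear, 35 members were called lower and the list's median was -0.73, and with age left out of the model 28 were called (median -0.72).

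Dynein assembly factors, cytoplasmic proteins that build the ciliary dynein arms, were lower in part. Of 13 measured members 5 were lower and 8 did not pass, with 6 lower when adjusted over the list alone. Daw1 was lower by 1.32 ± 0.35 on the log2 scale, Zmynd10 by 0.76 ± 0.30, Lrrc6 by 0.65 ± 0.24 and Pih1d2 by 0.64 ± 0.23. The list's median was -0.27 (camera adjusted p = 8.34e-12, and adjusted p = 0.181 with an estimated correlation).

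Of the genes of intraflagellar transport, the cargo system shared by motile and primary cilia, none of 39 passed, none passed when adjusted over the list alone, and 33 had a negative mean difference with a list median of -0.15. Ift80 (-0.55 ± 0.61), Ift172 (-0.46 ± 0.42), Ift81 (-0.42 ± 0.38) and Ift22 (-0.40 ± 0.28) had the most negative values. As a list they were lower by camera (adjusted p = 6.63e-07), with adjusted p = 0.575 with an estimated correlation.

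Regulators of multiciliation and centriole amplification showed no detectable difference. None of 24 passed in either adjustment, the median was -0.02 and the camera adjusted p was 0.746. Cetn2 (-0.21 ± 0.11), Myb (-0.20 ± 0.35), Cep164 (-0.19 ± 0.04) and Plk4 (0.19 ± 0.28) were the farthest from 0. Genes of the ependymal surface and of planar polarity behaved likewise. Among 30 members none passed over all genes and 1 was lower when adjusted over the list alone (list median -0.09, camera adjusted p = 0.212). Rarres2, a chemoattractant precursor, read -0.47 ± 0.07 with adjusted p = 0.114, and Cgnl1 (-0.28 ± 0.25), Acta2 (-0.28 ± 0.65) and the planar polarity gene Vangl2 (0.29 ± 0.20) were the other members farthest from 0.

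**Figure D2:**
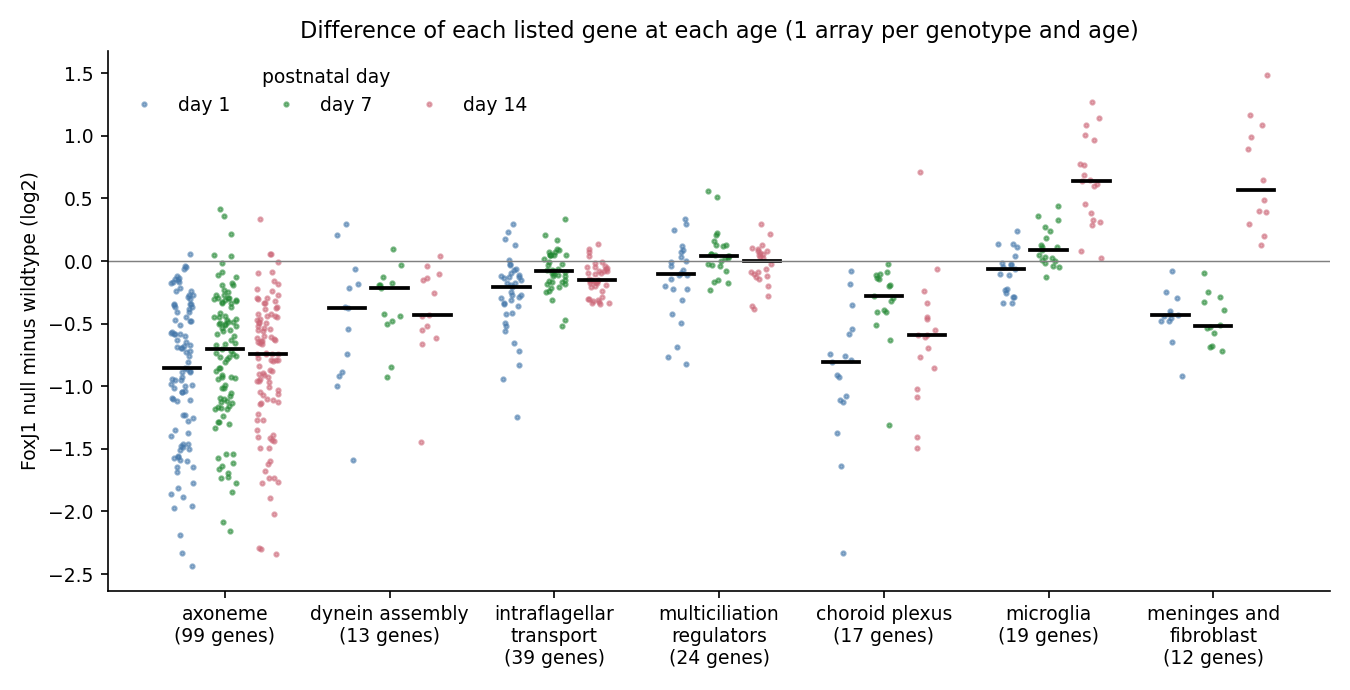
Null minus wildtype log2 difference (vertical axis) of each measured gene of 7 lists at postnatal days 1, 7 and 14, with 1 array per genotype and age; points are genes and bars are list medians. The axoneme medians lay between -0.85 and -0.70 at the 3 ages, and the microglia and meninges medians were 0.64 and 0.57 at day 14.

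Markers of the choroid plexus, the secretory epithelium that hangs in the ventricles, were lower in the null arrays. Of 17 members 3 were lower and 14 did not pass, with 15 lower when adjusted over the list alone. Ttr, the thyroid hormone carrier transthyretin, was lower by 2.47-fold (-1.31 ± 0.19, adjusted p = 0.000491), the tight junction gene Cldn2 by 1.72-fold (-0.79 ± 0.33, adjusted p = 0.0299), and the folate receptor Folr1, named because only 3 members passed, had a mean of -0.75 (adjusted p = 0.00858). Sostdc1 and the potassium channel Kcnj13 had values of similar size that varied more between ages, -1.25 ± 1.16 (adjusted p = 0.253) and -0.98 ± 0.73 (adjusted p = 0.131). The list median was -0.81 at day 1, -0.28 at day 7 and -0.59 at day 14 (camera adjusted p = 1.28e-22, and adjusted p = 0.271 with an estimated correlation). Quantile normalization applied again between the arrays ended the calls of Ttr (-0.53, adjusted p = 0.541) and Cldn2 (-0.76, adjusted p = 0.0833), as did leaving age out of the model for Cldn2 (adjusted p = 0.264).

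Markers of other cell types moved by smaller amounts, and no member of these lists passed over all genes. Microglia genes were higher as a list (18 of 19 positive, median 0.22, camera adjusted p = 2.10e-07, and adjusted p = 0.695 with an estimated correlation). Mpeg1 (0.62 ± 0.59), C1qc (0.41 ± 0.49), Ly86 (0.36 ± 0.63) and Cd68 (0.35 ± 0.75) led it, and the list was not called without the day 14 arrays (adjusted p = 0.455). Reactive gliosis genes were also higher (10 of 16 positive, median 0.11, adjusted p = 0.00598, and adjusted p = 0.695 with an estimated correlation), with Osmr at 0.50 ± 0.58 and S100a6 at 0.47 ± 0.36, C4b at 0.41 ± 0.67 and Serpina3n at 0.30 ± 0.97. This call too was lost without the day 14 arrays (adjusted p = 0.897). Oligodendrocyte genes were lower as a list (18 of 21 negative, median -0.19, adjusted p = 2.12e-05, and adjusted p = 0.269 with an estimated correlation), and 4 of them passed when adjusted over the list alone. Trf (-0.45 ± 0.10), Ermn (-0.38 ± 0.15), Cnp (-0.37 ± 0.15) and Gpr17 (-0.36 ± 0.14) had the most negative values, and the list's direction turned without the 2 high-Xist arrays (adjusted p = 0.307).

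Proliferation genes were lower as a list (27 of 30 negative, median -0.15, camera adjusted p = 1.02e-04, and adjusted p = 0.695 with an estimated correlation). Kif11 (-0.41 ± 0.23), Bub1b (-0.33 ± 0.29), Top2a (-0.32 ± 0.53) and Prc1 (-0.30 ± 0.36) led it, the list median was -0.36 at day 1, -0.08 at day 7 and 0.01 at day 14, and its direction turned without the day 1 arrays (adjusted p = 0.768). Astrocyte genes (17 of 21 negative, median -0.15, adjusted p = 0.00154) and neuroblast genes (16 of 20 negative, median -0.14, adjusted p = 0.00195) were lower as lists, each with adjusted p = 0.695 with an estimated correlation. Placed among random matched lists, the neuroblast medians of days 1, 7 and 14 stood at percentiles 47.0, 3.61 and 3.04. None lay beyond the random lists, whose own medians were -0.16 and -0.08 at days 7 and 14. The astrocyte genes Gja1 (-0.44 ± 0.55), Sparcl1 (-0.39 ± 0.48), Aldoc (-0.37 ± 0.26) and Acsbg1 (-0.36 ± 0.25) and the neuroblast genes Gad1 (-0.39 ± 0.25), Nrxn3 (-0.38 ± 0.31), Stmn1 (-0.35 ± 0.42) and Stmn2 (-0.32 ± 0.26) had the most negative values. Without the day 7 arrays neither list was called (adjusted p = 0.234 and 0.117). The astrocyte call also ended without the 2 high-Xist arrays (adjusted p = 0.366), and the neuroblast call without the day 14 arrays (adjusted p = 0.0636).

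Lists not called between the genotypes were radial glia and stem cell genes (median -0.04, camera adjusted p = 0.25), endothelial and mural genes (-0.05, adjusted p = 0.326), meningeal and fibroblast genes (-0.09, adjusted p = 0.37), neuron genes (adjusted p = 0.37), hedgehog signalling (0.02, adjusted p = 0.235), immediate early and stress genes (0.03, adjusted p = 0.264), interferon and MHC genes (-0.07, adjusted p = 0.383) and 2 erythroid genes (-0.07, adjusted p = 0.659). No member of these lists passed over all genes. Adjusted over the list alone, 1 neuron gene was higher and 1 interferon or MHC gene was lower. The neuron list had a median of -0.03 and a mean of 0.04, and camera placed it on the higher side. For the sex-chromosome list the median was -0.06 and the mean -0.07 while camera placed it on the higher side. Members with values farthest from 0 included Fabp7 (-0.69 ± 0.52, adjusted p = 0.205), a radial glia fatty acid binding protein, Ifit2 (-0.49 ± 0.23, adjusted p = 0.176), Ppp1r1b (0.47 ± 0.68, adjusted p = 0.835), Hsph1 (-0.47 ± 0.28, adjusted p = 0.272) and Rgs5 (-0.41 ± 0.62, adjusted p = 0.876). Of the 21 lists 10 were called with the preset correlation, and 0 with an estimated one.

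The authors' deposited list of 52 probe sets held genes lower in the null. Its first entries in the authors' order were Ttr, Prelp, Cldn2, Tm4sf1 and Clic6. In the fit made here the membrane gene Tm4sf1 was lower by 3.09-fold (-1.63 ± 0.50, adjusted p = 0.00143) and the matrix proteoglycan Prelp by 2.12-fold (-1.08 ± 0.48, adjusted p = 0.0145), while Clic6, an intracellular chloride channel gene, read -0.61 ± 0.42 (adjusted p = 0.205). All 52 probe sets were lower in the null array at all 3 ages. Of the 50 with 1 named gene, 43 were called lower and 7 were not called at the gene's brightest probe set, namely Apoe, Clic6, Dynll1, Hspa8, Kcnj16, Spata17 and Tmod1. For Hspa8 the listed probe set (10584572, mean -0.89) was not the brightest one tested (-0.80), and it was lower when every probe set was tested on its own (adjusted p = 0.0226). How the list was chosen is not given in the sources used here. It was drawn from these same arrays, so its direction is not independent evidence. A further 90 genes were called lower outside it, Fam216b and Ak7 among them. Of 181 genes lower at all 3 ages with a mean difference of -0.56 or below, 50 were in the authors' list. Prelp was not called after a further quantile normalization (-1.06, adjusted p = 0.053), with age left out of the model (-1.08, adjusted p = 0.204) or without the 2 high-Xist arrays (-0.92, adjusted p = 0.0536), and Tm4sf1 not in the latter pair of settings (-1.63 and -1.51, adjusted p = 0.16 and 0.055). Clic6 was called with Xist as a covariate (adjusted p = 0.0497).

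Each age could be compared only as 1 null against 1 wildtype array, with no replicate and no test, and the genes named here are those with the largest differences among genes above the median level. At day 1 the choroid plexus gene Sostdc1 had a difference of -2.33 in the null array, and Cfap44 -2.44, Tm4sf1 -1.94, Cfap43 -1.81, Nme5 -1.77 and 1700007K13Rik -1.65. Higher at that age were Arrdc4 (1.40), Dlk1 (1.26), Amy1 (1.12), Zfp804a (1.10), Txnip (1.07) and the Y-linked Eif2s3y (5.80). At day 7 Tm4sf1 (-1.89), Cfap43 (-1.69), Gpr179 (-1.63), Cfap44 (-1.54), Baiap2l1 (-1.45) and Eif2s3y (-5.74) were the lowest, and Neurod6 (1.02), G530011O06Rik (0.97), Mir99a (0.92), Lipa (0.89), Mir181b-1 (0.86) and C130030K03Rik (0.82) the highest. At day 14 Cfap43 (-2.02), Cfap44 (-1.68), Cfap54 (-1.62), Cfap52 (-1.50), Ttr (-1.49) and Sostdc1 (-1.41) were the lowest.

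Higher in the day 14 null array were Aldh1a2 (1.48), a retinoic acid synthesis enzyme of the meninges, G530011O06Rik (1.43), the complement inhibitor Serping1 (1.40), Ccn1 (1.34), the macrophage gene Mpeg1 (1.27) and the astrocyte filament gene Gfap (1.27). All 19 microglia genes and all 12 meningeal genes had positive differences at that age, with medians of 0.64 and 0.57. Both medians, and those of reactive gliosis (0.34), neuron (0.24), immediate early (0.22) and radial glia genes (0.16), lay above all 10000 random matched lists. These ranks do not allow for correlated list members or for the spread between captures, so they are descriptive. The endothelial and mural genes (0.18) stood at percentile 99.99, while the oligodendrocyte median (-0.19) lay below all random lists. Below all random lists lay the meningeal medians of day 1 (-0.43) and day 7 (-0.52) and the day 1 medians of endothelial and mural (-0.34) and radial glia genes (-0.22). Astrocyte genes stood below all random lists at day 7 (-0.38) and at percentile 97.3 at day 14 (0.03). The medians of the erythroid genes were -0.07, -0.33 and 0.18 at days 1, 7 and 14.

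Genes with an absolute difference of at least 1 numbered 150 at day 1 (120 lower in the null), 94 at day 7 (85 lower) and 116 at day 14 (77 lower), and 60, 29 and 43 above the median level. Across genes, differences correlated between days 1 and 7 with r = 0.027 (rho -0.021), between days 1 and 14 with r = 0.243 (rho 0.168) and between days 7 and 14 with r = 0.098 (rho -0.087); genes are not independent replicates.

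Expression in the captured tissue changed strongly between postnatal days 1 and 14. Many of these genes mark the other cell types a capture could hold. A shift in cell content was not separated from a change within ependymal cells. Myelin genes rose most, with Mag higher at day 14 by 4.80 ± 0.15 (SE from limma, n = 2 arrays per age), Mobp by 3.58 ± 0.15, Enpp6 by 3.29 ± 0.15, Mog by 3.26 ± 0.13 and Cnp by 3.20 ± 0.13. The transcription factor genes Neurod6 (-2.51 ± 0.28), Tbr1 (-2.03 ± 0.16) and Sox11 (-1.89 ± 0.13) fell. The progenitor matrix gene Tnc fell by 2.02 ± 0.20. Of 19938 genes 2751 changed, 1496 higher and 1255 lower at day 14. Bcas1, Klk1b22, Ugt8a, Mbp, Ermn, Lamp5 and Gpr37l1 completed the 12 greatest increases (2.94 to 3.20), and Trim67, Islr2, Mex3a, Stk32b, B3gnt5, Dpysl3, Sbk1 and St8sia2 the decreases (-1.98 to -1.77). For all 24 the limma adjusted p was 0.000695 or smaller. Their sign was the same in both genotypes because the rule named only such genes. The balance turned to 1463 higher and 1681 lower with each array centred on its median, and to 1505 and 1582 with Xist as a covariate. Across genes the change from day 1 to day 14 correlated between wildtype and null with r = 0.70 and rho = 0.604, over genes that are not independent replicates.

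Among the lists, oligodendrocyte genes had 16 of 21 members higher and 5 not passing (17 higher adjusted over the list alone), with a median of 2.44 (camera adjusted p = 5.87e-27, and adjusted p = 0.142 with an estimated correlation). All 30 proliferation genes fell, also when adjusted over the list alone (median -0.94, adjusted p = 4.34e-24, and adjusted p = 0.533 with an estimated correlation), with Top2a at -1.59 ± 0.21 and Mki67 at -1.58 ± 0.14. Astrocyte genes had 18 members higher, 2 lower and 1 not passing (19 and 2 adjusted over the list alone; median 0.98, adjusted p = 2.40e-14, and adjusted p = 0.533 with an estimated correlation). Ntsr2 (2.62) and Gfap (2.26) rose most, and Sox9 (-0.70) and Aldh1l1 (-0.68) fell. Microglia genes had 11 of 19 higher and 8 not passing, 17 higher adjusted over the list alone (median 0.73, adjusted p = 8.88e-11, and adjusted p = 0.584 with an estimated correlation). Ctss (1.42) and Itgam (1.25) rose most. Neuron genes had 14 higher, 2 lower and 7 not passing, 18 and 3 adjusted over the list alone (median 0.69, adjusted p = 3.87e-09, and adjusted p = 0.584 with an estimated correlation), with Penk at 2.44 and Bcl11b at -0.99. Neuroblast genes had 14 lower, 1 higher and 5 not passing, 15 and 2 adjusted over the list alone (median -0.62, adjusted p = 8.58e-09, and adjusted p = 0.584 with an estimated correlation), with Tubb2b at -1.60 and Gad1 at 0.70.

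Multiciliation regulators had 6 of 24 members lower at day 14 than at day 1, 9 adjusted over the list alone, and 18 not passing (median -0.27, camera adjusted p = 0.000426, and adjusted p = 0.533 with an estimated correlation). Those that fell were the centriole genes Stil (-1.01), Deup1 (-0.81), Plk4 (-0.79), Sass6 (-0.52) and Pcm1 (-0.48) and the mitotic kinase gene Nek2 (-0.63). Axoneme genes had 4 of 99 higher, 1 adjusted over the list alone, and none lower (median -0.01, adjusted p = 0.884). Dnah11 rose by 0.89, Stoml3 by 0.80, Nme5 by 0.76 and Dnal1 by 0.57. Of 13 dynein assembly genes Lrrc6 (0.75) rose and Ruvbl2 (-0.48) fell, in either adjustment (adjusted p = 0.956). Intraflagellar transport genes had 3 higher (Bbs2, Bbs5 and Ift22), 1 lower (Kif3b) and 35 not passing, 3 and 0 adjusted over the list alone (median 0.18, adjusted p = 0.0272, and adjusted p = 0.708 with an estimated correlation). That list was not called without the null day 1 (adjusted p = 0.569), null day 14 (0.0828) or wildtype day 14 array (0.0618). Ependymal surface genes went both ways, with 5 higher, S100b (2.43) and Aqp4 (1.91) among them, and 10 lower, Cd24a (-1.46) and Vangl2 (-0.85) among them, in either adjustment (median -0.13, adjusted p = 0.39).

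Hedgehog genes were lower (4 of 14 lower and 1 higher, 6 and 1 adjusted over the list alone; camera adjusted p = 0.00685, and adjusted p = 0.691 with an estimated correlation), with Gas1 at -0.77 and Gli3 at -0.71. Radial glia genes had 6 lower and 1 higher of 24, 6 and 2 adjusted over the list alone (adjusted p = 0.0268, and adjusted p = 0.713 with an estimated correlation), and Nes fell by 1.36. Immediate early genes had 7 of 20 higher, 8 adjusted over the list alone (adjusted p = 0.000586, and adjusted p = 0.683 with an estimated correlation), with Nr4a1 at 1.07 and Fosb at 0.89. Endothelial and mural genes had 3 of 19 higher in either adjustment (adjusted p = 0.00242, and adjusted p = 0.708 with an estimated correlation), with Slco1a4 at 2.06. Interferon and MHC genes had 2 of 17 higher, B2m (1.19) and Oasl2 (0.52), and 3 adjusted over the list alone (adjusted p = 0.00811, and adjusted p = 0.533 with an estimated correlation). Not called were reactive gliosis (2 higher, Gfap and C4b, 3 adjusted over the list alone, adjusted p = 0.062), choroid plexus (Aqp1 fell by 0.47, none adjusted over the list alone, adjusted p = 0.303), meningeal genes (0 in either adjustment, adjusted p = 0.344) and erythroid genes (0 in either adjustment, adjusted p = 0.956). In all 13 of 21 lists were called, and 0 with an estimated correlation. The radial glia list was not called with Xist as a covariate (adjusted p = 0.084), without the wildtype day 1 array (0.497) or without the wildtype day 14 array (0.731). Without the null day 1 or the null day 14 array, the endothelial and mural list (adjusted p = 0.256 and 0.351) and the interferon and MHC list (0.158 and 0.0543) were not called. Leaving out the null day 14 or null day 1 array lowered the count of changed genes to 1344 and 1739.

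From day 1 to day 7 few genes passed, 11 higher and 1 lower. Oligodendrocyte lineage genes Bcas1 (1.78), Gpr17 (1.30) and Enpp6 (1.27) rose, as did Gpr37l1 (1.697), Zfp979 (1.41), Lamp5 (1.33), Cpa6 (1.19), Syt10 (1.15), Tmem255a (0.95), Pla2g7 (0.92) and the water channel Aqp4 (1.45), while 1700093K21Rik fell by 1.20; the named rule did not cover this comparison, and all 12 are given. At an unadjusted p under 0.05, 2110 genes passed by limma. From day 7 to day 14 the number was 840, with 467 higher and 373 lower. The count from day 1 to day 7 was 0 without the wildtype day 7 array, 456 without the wildtype day 1 array and 188 without either day 14 array, and the count from day 7 to day 14 was 291 without the null day 7 array, 496 without the null day 14 array and 1587 without either day 1 array.

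**Figure D3:**
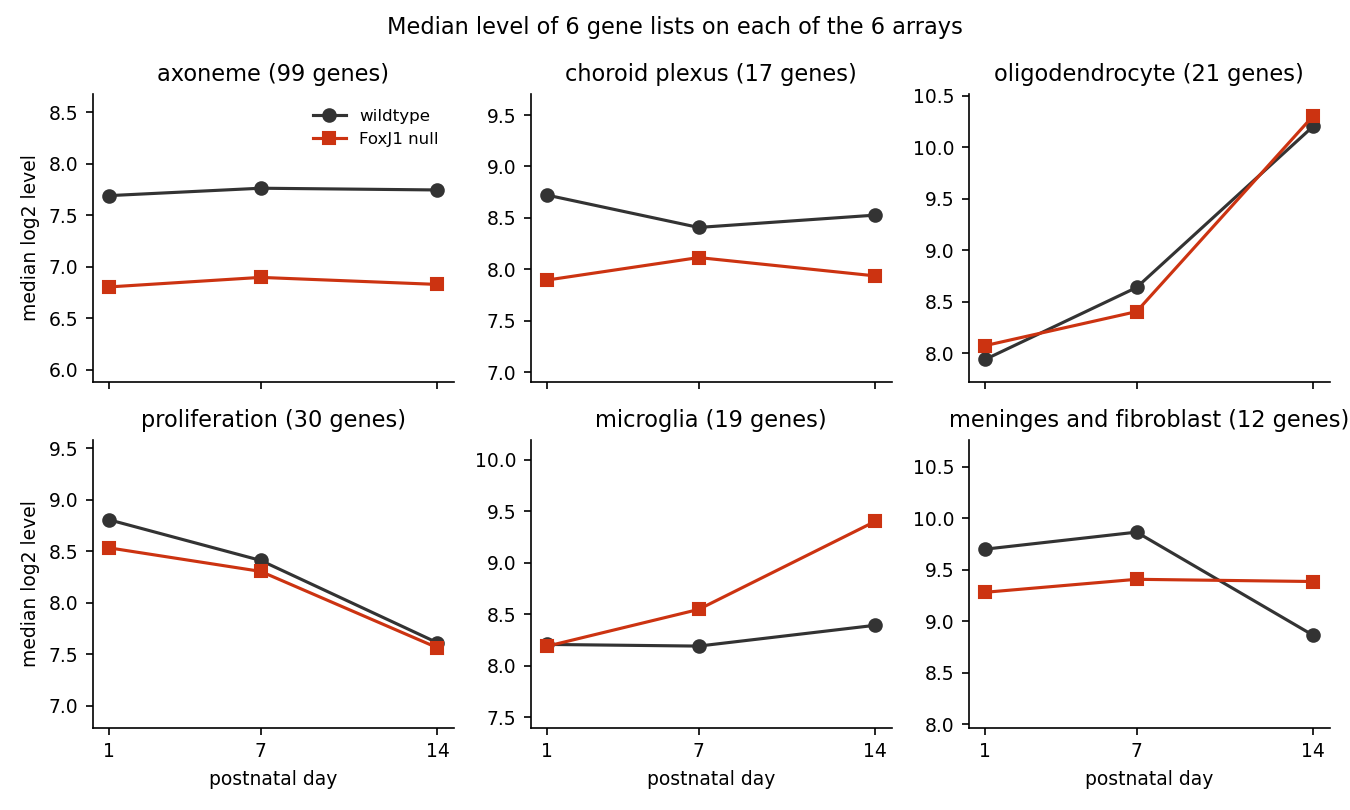
Median log2 level (vertical axis) of 6 gene lists on each of the 6 arrays against postnatal day (horizontal axis), with lines joining the arrays of one genotype. Oligodendrocyte medians reached 10.20 and 10.31 at day 14 in both genotypes, and the microglia median stood at 9.40 on the null day 14 array against 8.39 on the wildtype array.

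Whether age changed the 2 genotypes differently was tested as a difference of slopes. No single gene passed by limma (smallest adjusted p = 0.69), against 596 genes at an unadjusted p under 0.05, and a simulated total slope difference of 1 over the 13 days was likewise recovered in 0% of genes. Because none passed, genes were named by the smallest p in each direction. Those with a steeper rise in the null were the chemokine gene Ccl3 (0.16 per day), Gfap (0.15), the transporter Slc22a8 (0.14), the complement receptor C3ar1 (0.14), Anxa5 (0.13) and Stab1 (0.12), each with an adjusted p of 0.69. Values in the other direction were 2610005L07Rik (-0.10), Serpina1c (-0.10), H3c15 (-0.10), Calcr (-0.10), Tmem212 (-0.09) and Olfr1331 (-0.09), each with an adjusted p of 1.00. Greater slope differences with a larger p were not named by this rule, that of Xist (0.49) among them. The count rose to 9 without the null day 14 array, 3 without the null day 1 array and 1 without the null day 7 array.

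As lists, microglia genes had the clearest slope difference, with a median of 0.06 log2 per day and all 19 positive (camera adjusted p = 1.18e-20, and adjusted p = 0.267 with an estimated correlation); 7 passed when adjusted over the list alone. Their median level was 8.19, 8.55 and 9.40 on the null arrays of days 1, 7 and 14, and 8.21, 8.19 and 8.39 on the wildtype arrays. Meningeal and fibroblast genes followed (median 0.08, all 12 positive, adjusted p = 1.30e-16, and adjusted p = 0.445 with an estimated correlation), with 6 passing when adjusted over the list alone. Their level was 9.28, 9.41 and 9.39 on the null arrays and 9.70, 9.87 and 8.86 on the wildtype arrays, and without the wildtype day 14 array the list's direction turned (adjusted p = 0.511). Endothelial and mural genes (0.04 per day, 18 of 19 positive, adjusted p = 5.05e-13), reactive gliosis (0.03, 13 of 16, adjusted p = 1.07e-09), radial glia (0.03, 24 of 24, adjusted p = 1.67e-09) and proliferation genes (0.03, 27 of 30, adjusted p = 1.19e-08) were also positive, with adjusted p = 0.267, 0.267, 0.445 and 0.529 with an estimated correlation. In these lists 1, 4, 1 and 0 genes passed when adjusted over the list alone. The proliferation list turned without the null day 1 array (adjusted p = 0.0197), and the radial glia list was not called without the wildtype day 14 array (adjusted p = 0.643).

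In total 14 of 21 lists were called, 13 with a positive and 1, neuroblast genes, with a negative slope difference, and 0 with an estimated correlation. The remaining lists had an adjusted p between 0.00119 and 0.0262 with the preset correlation, and each changed its call or its direction in at least 1 setting that left out an array of day 1 or day 14. With Xist as a covariate 9 lists were called, and the choroid plexus, ependymal surface, interferon and MHC, intraflagellar transport and neuroblast lists were not. The axoneme list was not called (58 of 99 positive, median 0.00, adjusted p = 0.176), nor were dynein assembly (adjusted p = 0.286), multiciliation regulators (0.143), oligodendrocyte (0.187), hedgehog (0.789) and erythroid genes (0.218).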

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

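The tests of the 3 patterns weighed in this part were chosen after the results were seen; the list tests and the other splits of the arrays were not. A difference between genotypes in slope over age put 14 gene lists here. With the preset correlation the limma camera adjusted p was 1.18e-20 for microglia, 1.30e-16 for meningeal, 5.05e-13 for endothelial and mural, 1.07e-09 for reactive gliosis, 1.67e-09 for radial glia, 1.19e-08 for proliferation and 0.00119 for immediate early genes. It was 0.0228 for each of the astrocyte, choroid plexus, interferon and MHC, intraflagellar transport and neuron lists, 0.0235 for neuroblast genes and 0.0262 for ependymal surface and polarity genes. None was called with an estimated correlation (smallest adjusted p = 0.267). Outside the named genes, 9 of 13768 probe sets were called between the genotypes in a limma fit of all probe sets, 6 lower and 3 higher in the null. That fit called 58 probe sets in all, those of named genes included.

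Genes of the axoneme and of the choroid plexus were both lower in the null arrays. A capture with less choroid plexus could lower both, and in step if the plexus supplied both signals, a premise that was not tested. The day 7 difference was 0.88 of the mean of days 1 and 14 for the axoneme (0.715 to 1.04 over resampled genes). For the choroid plexus it was 0.40 (0.192 to 0.572), so the list medians did not move in step. These ranges are over genes that share 1 array pair per age and do not measure the spread between captures. Because the choroid plexus genes were also uneven at day 7, the ratio does not decide whether capture gave the axoneme pattern. For the choroid plexus genes themselves, 16 of 17 were lower at both days 1 and 14. Less choroid plexus tissue in the null captures would give this, but the count restates the pattern and is no separate evidence for it. At day 7 all 17 were lower with a median of -0.28, but unevenly: Ttr (-1.31) and Folr1 (-0.63) stood apart from Sostdc1 (-0.02) and Kcnj13 (-0.20). Genotype remains a biological explanation for both groups, and these arrays do not separate it from capture for either.

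Microglia, meningeal and gliosis genes were higher in the null at day 14. A lower share of ependymal cells could raise the markers of every other cell type, but these moved apart. Oligodendrocyte and neuroblast genes, lists picked after their values were seen, had a median of -0.1656 (SE 0.0414 over genes of 1 array pair). The medians were 0.24 for neuron, 0.18 for endothelial and 0.16 for radial glia genes. Among random matched lists the oligodendrocyte median lay below all, while the neuroblast median stood at percentile 3.04. With lists picked in this way and 1 array pair, the comparison does not decide for or against a lower share. Animals of different sex are excluded for this pair, since Xist differed by 0.14. More meningeal tissue in the null capture stays open: the day 14 null level was -0.0216 relative to the higher of the other null arrays, while the wildtype level changed by -0.84 from day 1 to day 14. A response to the loss of Foxj1 is the biological explanation, and with 1 array per genotype at that age it was not tested.

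High Xist and low Y genes marked the wildtype day 1 and null day 7 arrays. Female animals fit: the smallest gap of the 3 Y genes to the other arrays was 3.73 and that of Xist 6.52. Pools with a sizeable share of males would have left Y transcripts at a level less than 3 log2 units lower, so the gap of 3.73 argues against such pools. A small share of males is not excluded, since the Y genes stood at percentiles 4.2 to 8.2 on these arrays, among the dimmest genes. A swap of these 2 arrays with each other would leave the pattern as it is, so it cannot explain the Xist levels. The median axoneme level of the null day 7 array, 6.90, was 0.0805 above the mean of the other null arrays. Relative to the mean of the wildtype arrays of days 7 and 14 it was -0.8581. The wildtype day 1 array read 7.69, against 7.76 and 7.75 on the other wildtype arrays. Both arrays thus stood with their labelled genotype, which argues against such a swap. The labels do not give sex per array, and the genotype gives no biological explanation for the pattern.

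The 6 arrays were also divided in all 10 ways into 3 and 3, with the same fits. As many as 134 genes for the genotype comparison were called in 1 of 10 splits, the real one (highest other 2), and as many as 10 lists in 7 of 10 (highest other 13). For slopes at least 14 lists were called in 2 of 10 (highest other 14), while the real split called 0 genes, a count that all 10 of 10 splits must reach, so that comparison decides nothing (highest other 27). Because 10 splits are too few for a share under 0.05, the smallest being 0.1, chance is neither excluded nor accepted for the other 3 counts. Nor are the other splits free of the genotype difference: 6 of the 9 divide the arrays of only 1 age and so carry that age's null minus wildtype difference, and the other 3 swap the genotypes at 1 age. The split with 27 genes swaps the genotypes at day 14, while the split that swaps them at day 1 called 0. In either split a constant genotype difference would appear as a slope difference, so the 27 calls need not reflect other structure among the arrays. Why the counts differed was not tested. The split that tied at 14 lists swaps the genotypes at day 7 and puts both high-Xist arrays in one group. With Xist as a covariate the real split gave 9 lists.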

How the results depend on the processing

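The direction of the genotype calls held in every alternative that tested them for Fam216b, Dnah12, Bbox1, Ak7 and the 8 other greatest decreases, with a limma adjusted p of 0.0498 or smaller, and the 24 named age genes kept their calls wherever tested (0.0169 or smaller). The 134 genes became 61 without the lowest tertile by level, 16 above the median level (fewer genes tested in both), 45 with age left out and 66 without the wildtype day 1 and null day 7 arrays with age linear (both choices changed together; the cause was not tested), against 98 to 156 in other settings and 135 to 186 by leave-one-out. With each probe set on its own 242 probe sets were called, in 164 genes. When the probe sets without 1 named gene were added to that fit, the count fell to 58 probe sets in all, and the cause was not tested. Of the called lower genes 113 of 133 lay below the median level; whether low signal limits this count was not tested. From day 1 to day 7, 12 genes became 6 with a further quantile normalization, 67 with centring, 77 above the median level, 0 with genotype left out (1953 unadjusted), and 0 (wildtype day 7; 2718 unadjusted) to 456 (wildtype day 1) by leave-one-out; the cause was not tested. Leave-one-out gave 1344 (null day 14) to 3255 for day 14 against day 1, 291 (null day 7) to 1587 for day 14 against day 7, and 0 to 9 (null day 14) for slopes, where an age left with 1 array is assumed to vary like the others. Above the median level the differences of at least 1 at single ages fell from 360 to 132 (60, 29 and 43 at days 1, 7 and 14), with fewer genes tested.

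For the lists, an estimated correlation gave 0 calls in all 3 comparisons. Correlated members do not account for this in every list. For genotype, the estimates for dynein assembly (-0.0511) and oligodendrocyte genes (-0.0236) lay below the preset 0.01. Their unadjusted camera p still rose, from 1.19e-12 to 0.0172 and from 6.05e-06 to 0.0384. The cause was not tested further. Leave-one-out gave 9 to 12 lists for genotype, 11 to 14 for age and 8 (wildtype day 14) to 15 for slopes, and Xist as a covariate gave 9 for slopes. By camera adjusted p, the genotype direction turned for proliferation without the day 1 arrays (0.768; leave-one-out range 1.61e-07 to 0.768) and for oligodendrocyte genes without the wildtype day 1 and null day 7 arrays (0.307; range over all alternatives 1.57e-05 to 0.307). Slope directions turned for choroid plexus without the null day 1 array (0.000458; leave-one-out 7.02e-08 to 0.877) and with Xist as a covariate (0.545), for intraflagellar transport (0.0123; 3.46e-06 to 0.294) and proliferation (0.0197; 1.27e-15 to 0.672) without the same array, and for neuroblast genes without the wildtype day 1 array (0.972; 0.0017 to 0.972). They also turned for astrocyte (0.439; 0.000128 to 0.511), immediate early (0.349; 5.21e-07 to 0.349) and neuron genes (0.0366; 2.86e-07 to 0.643) without the null day 14 array, and for meningeal (0.511; 2.10e-32 to 0.511) and neuron genes (0.643) without the wildtype day 14 array. The cause was not tested. Microglia, endothelial and mural, and reactive gliosis slopes were called in 7 of 8 alternatives each, all but the estimated correlation (0.267). Ependymal surface and polarity slopes (highest 0.767) and interferon and MHC slopes (highest 0.9945) were called in 3 of 8 each, and radial glia slopes in 6 of 8 (highest 0.643).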

Other observations

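The grouping by symbol stem and the genes and counts singled out in this part were chosen after the data were seen. Outside the fixed lists, 68 of the 133 genes called lower in the null remained. Armc3 (-1.53 ± 0.12, SD over 3 ages), Maats1 (-1.52 ± 0.14), Ccdc146 (-1.35 ± 0.08) and the kinase gene Nek11 (-1.22 ± 0.30) were among them. When genes were grouped by the stem of their symbol, 4 of 590 stems outside the lists held more lower genes than chance gives by Fisher's exact test: Lrrc with 5 of 64 (adjusted p = 0.00172), Cfap with 3 of 15 (adjusted p = 0.00532), Kif with 3 of 32 (adjusted p = 0.037) and Gas with 2 of 8 (adjusted p = 0.049), the last a shared stem without a shared function. The kinesin genes Kif6 (-0.84 ± 0.19), Kif9 (-0.83 ± 0.26) and Kif27 (-0.60 ± 0.13) were lower, as were the leucine-rich repeat genes Lrrc74b (-1.62 ± 0.15) and Lrrc34 (-1.19 ± 0.19), Cfap161 (-1.46 ± 0.14) and Cfap299 (-1.10 ± 0.29).

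Several genes were represented by many probe sets. Tested singly by limma, 29 of 33 probe sets of the axonemal dynein gene Dnah3 were lower (median -1.29, brightest -0.65), 20 of 22 of the sperm flagellar gene Spef2 (median -1.55, brightest -0.51 with adjusted p = 0.121) and 15 of 27 of Ccdc180 (median -0.66, brightest -0.14). In all, 164 genes had a called probe set, and 30 of them were not called in the fit of 1 probe set per gene, 11 of these having over 1 probe set.

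Of the 133 genes lower in the null, 14 rose from day 1 to day 14 and 0 fell, Syt10 (1.43), Syne1 (1.23), Akr1c18 (1.01) and Dnah11 (0.89) rising most, and the median absolute change was 0.142 against 0.165 in the other genes, a difference that was not tested.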
